A study of Mus musculus with 2 samples.

How the data were processed

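RNA was sequenced from the retinal pigment epithelium (RPE)-choroid, the pigmented cell layer beneath the retina with the vascular coat behind it. The tissue came from untreated mice 11 to 13 months old. Per the labels' protocols, eyes were enucleated, the anterior segment and the retina were taken off, RNA of 2 eyes was pooled per library, and polyA-enriched libraries were made with an Illumina TruSeq kit. The labels list 3 animals in each of 2 groups. One group is labelled AhR -/- and carries a targeted allele of the aryl hydrocarbon receptor gene (Ahr, strain B6.129-AhR^tm1Bra/J). The other is labelled C57BL6/J. Each GEO entry stands for 1 group, and each animal has its own column in the count table.

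The deposited table holds whole-number gene counts per animal, which the authors made with HTSeq after alignment with TopHat and Bowtie to mm10, per the submitters' processing notes. Versions, the gene annotation and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart. A second deposited table holds the authors' edgeR results: log2 fold changes, mean log2 CPM, p-values and FDR values. Its log2 fold changes are coded as wild type over knockout, and their sign was turned here so that positive values mean higher in the knockout-labelled libraries.

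The count table has 23420 gene rows and 5 rows of the counting tool's own tallies. The tallies were left out of library sizes and tests. Shares were taken of each library's sum over all rows, tallies included. The share assigned to no gene was 15.5% ± 0.99 in knockout-labelled and 16.4% ± 0.39 in wild-type libraries (SD, n = 3 each). The ambiguous share was 0.55% ± 0.21 and 0.49% ± 0.01 (SD, n = 3 each). The tallies for low alignment quality and for unaligned reads were 0 in all 6 libraries. In the gene column, 27 names read as dates, a change spreadsheets make to gene symbols, and 4 rows share a name with another row; these genes are not named. Gene counts summed to between 18058725 and 28692624 per library. Each pair of libraries differed by more than counting noise.

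Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group (minimum count 10, minimum total 15), TMM factors, glmQLFit and glmQLFTest with genotype as the only term, and Benjamini-Hochberg adjustment over the 15796 genes tested. A gene was called at an adjusted p under 0.05 with no minimum fold. Log2 fold changes are knockout-labelled over wild type. Their standard errors (SE) were taken as the absolute log2 fold change divided by the square root of the test's F value. Levels are CPM, the deposited count of a gene scaled by the TMM-adjusted library size. The common biological coefficient of variation was 0.28.

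Before the data were examined, 16 gene lists and 24 lists of cell type or tissue markers were fixed. The 39 lists with at least 3 tested members were tested with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01, adjusted over all 39. The list of mitochondrially encoded genes had 0 tested members. Also fixed were the test of genes within 10 Mb of Ahr (two-sided Fisher's exact test) and the rule for naming genes. The rule took Ahr, and, among called genes with a mean CPM of at least 1 and no overlap between the groups, the 12 with the largest rise and the 12 with the largest fall. From each list it took up to 4 called members, or, where no member was called, up to 2 members with the highest mean CPM, which are given as values. Predicted genes, ribosomal protein genes and pseudogenes were counted but not named. List members named because they passed when adjusted over the list alone lie outside this rule and were chosen after their values were seen. The part of the rule that goes by level takes 69 uncalled genes, of which 19 are named. These 19 were picked after their values were seen, partly to leave out genes near 0 whose sign turned between settings. The sign turned in at least 1 alternative for 6 of the 19 and for 29 of the 50 left out, so the named genes understate how often uncalled genes turned. A few values are not reported here.

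Alternatives fixed in advance were DESeq2 size factors (RLE), upper-quartile factors, no filter beyond 1 count, a filter of CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, the edgeR exact test, the animal number as a block, each library left out in turn, other thresholds, camera with an estimated correlation, and fry. Chosen after seeing the data were a correction for transcript GC content, sex as a covariate, and the mean log2 CPM of the cornea and conjunctiva markers as a covariate. Sex was read from Xist and Y-linked genes: animal 1 was female in both groups and the others were male. The GC correction removed, through offsets, each library's lowess trend (span 0.3) of log2 CPM on transcript GC content, fitted on genes with a mean log2 CPM above 2. GC values and coordinates came from GENCODE M21 (GRCm38, the same assembly as mm10), matched by symbol; 15638 of the 15796 tested genes (99.0%) had a GC value.

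The procedure was tested on simulated counts for the knockout-labelled against wild-type comparison. The quasi-likelihood test on 15506 simulated genes recovered 57% of genes changed 2-fold and 97% of those changed 4-fold, with 10 false calls among 164. The edgeR exact test recovered 77% and 99%, with 39 false calls among 215. A GC trend was also simulated (15491 genes), stronger than that of the data (Spearman's correlation across unchanged genes -0.51, against -0.34 across all genes in the data). It was the same in all libraries of a group, whereas in the data knockout-labelled animal 1 ran with the wild type. With this trend false calls were 36 of 184 for the quasi-likelihood test, 124 of 293 for the exact test, and 13 of 161 for the quasi-likelihood test after the GC correction. These counts need not hold for the data.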

Results

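The series title ties the aryl hydrocarbon receptor, a ligand-activated transcription factor, to vessel growth in the choroid. Its single comparison asks which transcripts of the RPE-choroid differ between AhR knockout and wild-type mice of the same age. Polyadenylated RNA was counted in 3 animals per group, with RNA of 2 eyes pooled per library. Gene counts summed to 24359728, 18058725 and 24581160 in knockout-labelled animals 1, 2 and 3. They summed to 26289851, 24715580 and 28692624 in wild-type animals 1, 2 and 3.

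Ahr (chromosome 12, 35497974 to 35535038, minus strand, GRCm38) was counted in every library. Its CPM was 41.4, 45.4 and 40.6 in knockout-labelled animals 1 to 3, against 19.7, 20.2 and 26.0 in wild-type animals 1 to 3. The group means were 42.5 ± 2.55 and 22.0 ± 3.51 (SD, n = 3 each), and the libraries did not overlap. The log2 fold change was 0.95 (SE 0.16), which did not pass in edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.0991). It passed in DESeq2 (adjusted p = 0.000208), in the edgeR exact test (adjusted p = 0.000546) and in edgeR without knockout-labelled animal 1 (adjusted p = 0.0258). Over all alternatives the adjusted p of Ahr ran from 0.000208 to 0.374. A targeted allele of this kind removes part of the gene, and a count over the whole gene cannot show whether that part is missing, so it does not check the labels. The direction goes against a loss of the transcript. The libraries are therefore called knockout-labelled, and every direction below rests on those labels.

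**Figure D1:**
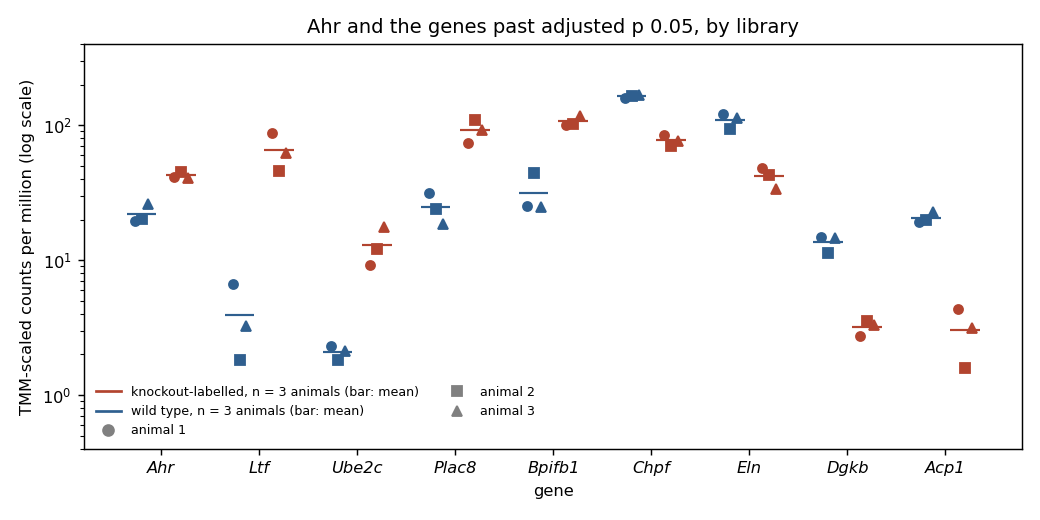
TMM-scaled CPM (log axis) of Ahr and the 8 called genes in each of the 6 libraries, with a bar at each group mean (n = 3 animals). For all 9 genes the groups do not overlap, and Ahr lies higher in the knockout-labelled libraries (means 42.5 and 22.0).

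Of 15796 genes tested, 8 were called, 4 higher and 4 lower in the knockout-labelled libraries. Ltf, which encodes lactotransferrin, an iron-binding protein of neutrophil granules and mucosal secretions, rose most. It went from 3.89 ± 2.46 to 65.4 ± 21.1 CPM (SD, n = 3 each), a log2 fold change of 4.07 (SE 0.44, edgeR adjusted p = 0.0389). Plac8 rose from 24.7 ± 6.64 to 91.5 ± 17.4 CPM (log2 fold change 1.89). Bpifb1, a secreted protein of mucosal epithelia, rose from 31.3 ± 11.2 to 107 ± 9.21 CPM (1.77; SD, n = 3 each, edgeR adjusted p = 0.0415). Ube2c, a ubiquitin-conjugating enzyme of the cell cycle, rose from 2.07 ± 0.24 to 12.9 ± 4.26 CPM (2.64), but its locus overlaps that of the muscle gene Tnnc2 and its count is uncertain. Eln, which encodes elastin, the core of the elastic layer of Bruch's membrane, fell from 109 ± 13.9 to 41.7 ± 7.45 CPM (-1.39, SE 0.16, edgeR adjusted p = 0.0389). Chpf, an enzyme of chondroitin sulphate synthesis, fell from 163 ± 3.29 to 77.1 ± 6.69 CPM (-1.08). Acp1, a small protein tyrosine phosphatase, fell from 20.6 ± 1.97 to 3.02 ± 1.37 CPM (-2.76). Dgkb, a diacylglycerol kinase, fell from 13.6 ± 2.08 to 3.18 ± 0.41 CPM (-2.10; SD, n = 3 each). The locus of Acp1 overlaps that of Alkal2, so its count is uncertain too.

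In GRCm38, Ltf lies at 111019271 to 111042767 of chromosome 9 and Chpf at 75474569 to 75479307 of chromosome 1. Plac8 lies at 100553725 to 100572245 and Eln at 134702593 to 134747323 of chromosome 5. Bpifb1 lies at 154190818 to 154220369 and Ube2c at 164769898 to 164778822 of chromosome 2. Acp1, at 30893326 to 30911589, and Dgkb, at 37817726 to 38634239, are on chromosome 12 within 10 Mb of Ahr.

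At an unadjusted p under 0.05 the same test held 2238 genes (14.2%). The groups did not overlap for 3158 of the 15796 genes. Chance gives 10% as an average over splits of the 6 libraries into 3 and 3. Genes vary together and a single split can exceed that average, so neither count alone shows an effect of genotype. In the other splits, 231 to 1779 genes had an unadjusted p under 0.05. The 1779 came from knockout-labelled animal 1 and wild-type animals 2 and 3 against the rest. The count of calls turned on single libraries, on the tool and on the terms of the model. It was 795 without knockout-labelled animal 1, 9 without wild-type animal 1 and 1 without wild-type animal 2. Without knockout-labelled animal 2, knockout-labelled animal 3 or wild-type animal 3 the edgeR test called 0 genes, with 1516, 1719 and 1738 at an unadjusted p under 0.05. The edgeR exact test called 352 genes and DESeq2 493. In both groups animal 1 was female and animals 2 and 3 were male, and with sex as a covariate Ltf was the 1 gene called, as it was with the animal number as a block. Ube2c was not called with limma-voom or with the cornea marker covariate, and Dgkb was not called with limma-voom. After the GC correction 6 genes were called, and Eln (log2 fold change -1.15), Chpf (-0.72) and Acp1 (-2.87) were not among them. The authors' deposited table lists 392 genes at an FDR under 0.05, 268 higher and 124 lower in the knockout. Of the genes at that FDR in the authors' deposited table, 377 were tested here. All 377 had the same direction as in the authors' deposited table and an unadjusted p under 0.05 in the edgeR test, and 8 were called.

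Log2 fold changes moved with the GC content of the transcripts: across 15638 genes, which are not independent replicates, Spearman's correlation was -0.34. The median log2 fold change was 0.17 in the decile of genes with the lowest GC content (median 40.2%) and -0.28 in the decile with the highest (60.0%). Relative to each gene's mean over the 6 libraries, values fell with GC content in knockout-labelled animals 2 and 3 and rose in knockout-labelled animal 1 and the wild type. Being relative, these values do not place the trend in particular libraries.

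**Figure D2:**
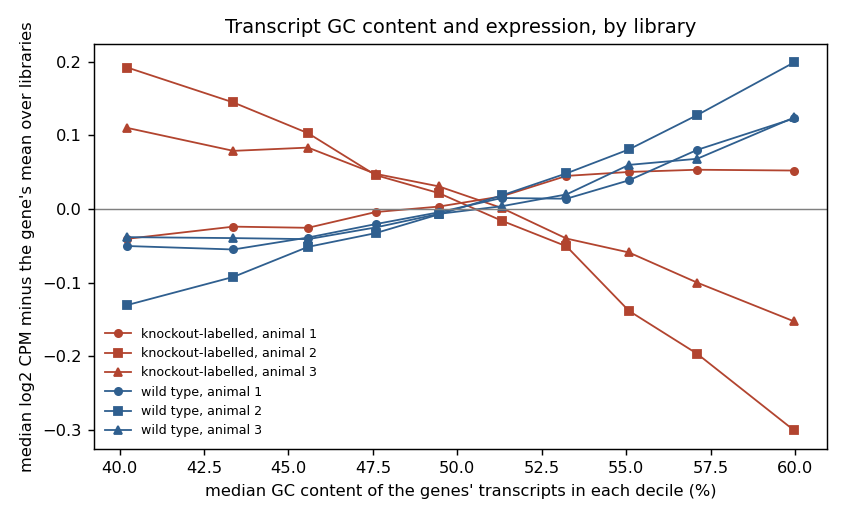
Median log2 CPM minus the gene's mean over the 6 libraries, for deciles of genes ordered by the GC content of their transcripts (x axis, median GC in percent), 1 line per library. In knockout-labelled animals 2 and 3 the values fall with GC content, to -0.30 and -0.15 in the highest decile, while in the other 4 libraries they are higher in the highest decile than in the lowest, at 0.05 in knockout-labelled animal 1 and up to 0.20 in the wild type.

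Genes of the extracellular matrix were lower as a group in the knockout-labelled libraries. The list of Bruch's membrane and stromal matrix genes, 38 members tested, had a median log2 fold change of -0.36 (camera adjusted p = 9.71e-09). With an estimated correlation the list was not called (adjusted p = 0.55), as held for every list here. That estimate was 0.14 for the matrix list and 0.64 for endothelial markers. Over the called lists it ran from 0.03 (matrix proteases) to 0.96 (erythroid markers), above the preset of 0.01. List directions here and below therefore describe these 6 libraries. Whether any list differs beyond the spread between animals stays open. Eln fell when adjusted over all genes, and 8 members, Eln included, were lower when adjusted over the list alone. The others were the collagen genes Col1a1 (log2 fold change -1.17, 322 ± 63.1 against 725 ± 124 CPM, SD, n = 3 each), Col6a2 (-0.81), Col5a1 (-0.73), Col1a2 (-0.65) and Col4a2 (-0.43), and Fbln2 (-0.69) and Hspg2 (-0.50), which encode fibulin 2 and perlecan. The list has a median GC content of 53.2%, and its median after the GC correction was -0.24 (camera adjusted p = 2.81e-06). With that correction the log2 fold change of Hspg2 went to -0.19 and that of Col4a2 to -0.13.

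Matrix proteases and inhibitors had a median of -0.19 over 25 members (camera adjusted p = 0.0034; adjusted p = 0.55 with an estimated correlation), with 0 called. The elastin cross-linking enzyme Loxl1 (-0.85) and the procollagen protease Adamts2 (-0.72) were lower when adjusted over the list alone. After the GC correction the log2 fold change of Loxl1 was -0.53. Timp3, which encodes a matrix-bound protease inhibitor, stood at 3413 ± 1011 and 4776 ± 260 CPM (SD, n = 3 each). Sclera and cartilage markers were lower (median -0.38 over 8 members, camera adjusted p = 0.0137; adjusted p = 0.628 with an estimated correlation). Of these 0 were called, and Chad (-1.27) and Fmod (-0.74) passed adjusted over the list alone. Fibroblast markers had a median of -0.14 over 9 members (camera adjusted p = 0.0251; adjusted p = 0.55 with an estimated correlation). Of these 0 were called, Col1a1 and Col1a2 were lower when adjusted over the list alone, and Dcn, encoding decorin, stood at 5842 ± 248 and 6418 ± 630 CPM (SD, n = 3 each). The calls of the sclera and fibroblast lists ended with the GC correction (adjusted p = 0.0792 and 0.0626). The sclera median went to -0.18, nearer 0, but the fibroblast median went to -0.24, farther from 0. With the cornea marker covariate both lists were lower still, with medians of -0.64 and -0.61 (adjusted p = 5.33e-06 and 0.000724), and Chad was at -1.91. They also ended without knockout-labelled animal 1 (0.32 and 0.175), wild-type animal 1 (0.0879 and 0.0617) or wild-type animal 3 (0.121 and 0.0612), and that of fibroblasts without knockout-labelled animal 3 (0.12).

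Vascular genes were lower too. Of 33 angiogenic factors and receptors, 0 were called and 6 were lower when adjusted over the list alone. These were Pgf, encoding placental growth factor (log2 fold change -0.85, 63.3 ± 7.15 against 114 ± 20.7 CPM, SD, n = 3 each), Notch4 (-0.82), Dll4 (-0.76), Ctgf (-0.69), the pericyte receptor gene Pdgfrb (-0.54) and Flt4 (-0.50). The list's median was -0.22 (camera adjusted p = 0.000439; adjusted p = 0.55 with an estimated correlation). Endothelial markers had a median of -0.40 over 13 members (camera adjusted p = 0.000231; adjusted p = 0.568 with an estimated correlation). Of these 0 were called, and Cldn5 (-0.80), Egfl7 (-0.77) and Erg (-0.64) passed adjusted over the list alone. Their mean log2 CPM was 6.38 in knockout-labelled animal 1, 5.98 and 5.78 in animals 2 and 3, and between 6.41 and 6.45 in the wild type. Markers of pericytes and smooth muscle (median -0.24, camera adjusted p = 0.0251; adjusted p = 0.685 with an estimated correlation) and of Schwann cells (median -0.30, camera adjusted p = 0.0105; adjusted p = 0.55 with an estimated correlation) were lower. In each 0 members were called and 1 passed adjusted over the list alone, Tagln (-0.66) and Prx (-1.12). After the GC correction the log2 fold changes of Notch4, Flt4 and Cldn5 were -0.51, -0.33 and -0.51. With the cornea marker covariate the angiogenic list kept its call at a median of -0.11 (adjusted p = 0.00269), and Egfl7 was at -0.49. With that covariate the endothelial, pericyte and Schwann cell lists were not called (medians -0.21, -0.13 and -0.14, adjusted p = 0.0605, 0.251 and 0.318). The pericyte list was also not called without knockout-labelled animal 3 (0.21), wild-type animal 1 (0.101) or wild-type animal 2 (0.0513).

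Neutrophil markers were higher in the knockout-labelled libraries. Of 5 tested members 4 lay above 0, with a median log2 fold change of 2.82 (camera adjusted p = 7.93e-08; adjusted p = 0.55 with an estimated correlation). Ltf was called. S100a9 and S100a8, which encode the subunits of calprotectin, also passed adjusted over the list alone, at 10.7 ± 4.29 against 1.29 ± 1.18 CPM and 5.63 ± 3.70 against 0.80 ± 0.36 CPM (SD, n = 3 each). Chemokines, cytokines and adhesion molecules had a median of 0.62 over 31 members (camera adjusted p = 0.00347; adjusted p = 0.55 with an estimated correlation). Of these 0 were called and 1 passed adjusted over the list alone, the monocyte chemoattractant gene Ccl7 (6.29 ± 1.72 against 1.02 ± 0.44 CPM, SD, n = 3 each). Complement genes were higher (median 0.18 over 23 members, camera adjusted p = 0.0105; adjusted p = 0.568 with an estimated correlation), with 0 called and Cd59a (0.55) and C3ar1 (0.59) past the threshold adjusted over the list alone. The complement median was 0.36 after the GC correction (adjusted p = 0.00226) and 0.42 with the cornea marker covariate (1.58e-06). Interferon response and MHC genes had a median of 0.20 (camera adjusted p = 0.00379; adjusted p = 0.55 with an estimated correlation) and 0 members past either threshold. Of the 29 interferon and MHC genes tested, 24 lay above 0 and 5 below. Rsad2 of that list (log2 fold change 1.61) lies within 10 Mb of Ahr, so linked sequence may affect it. B2m stood at 971 ± 65.5 and 678 ± 148 CPM and H2-K1 at 440 ± 97.1 and 304 ± 56.2 CPM (SD, n = 3 each). Oxidative stress genes had a median of 0.25 (camera adjusted p = 0.00347; adjusted p = 0.55 with an estimated correlation), also with 0 members past either threshold, and Gpx3 stood at 932 ± 231 and 643 ± 283 CPM (SD, n = 3 each). Without knockout-labelled animal 1, the library highest in erythroid transcripts, the complement, chemokine, interferon and oxidative stress lists were not called (adjusted p = 0.191, 0.105, 0.0811 and 0.104). Without wild-type animal 3 the interferon and oxidative stress lists were not called (0.0612 and 0.0984). Markers of macrophages (median 0.20, adjusted p = 0.12; 0.727 with an estimated correlation) and lymphocytes (median 1.07, adjusted p = 0.0597; 0.685 with an estimated correlation) were not called. Macrophage markers were called as higher with the GC correction (0.0482), with the cornea marker covariate (0.00038, median 0.33), and without knockout-labelled animal 3 (0.0204) or wild-type animal 2 (0.0238). Lymphocyte markers were called as higher with the stricter filter (0.00388), the replicate block (0.018) and the cornea marker covariate (0.00391), and without knockout-labelled animal 3 (0.00277) or wild-type animal 2 (0.0226). Lyz2, of macrophages, stood at 1858 ± 341 and 1573 ± 483 CPM and the plasma cell gene Igj at 7.36 ± 0.89 and 3.32 ± 2.04 CPM (SD, n = 3 each).

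**Figure D3:**
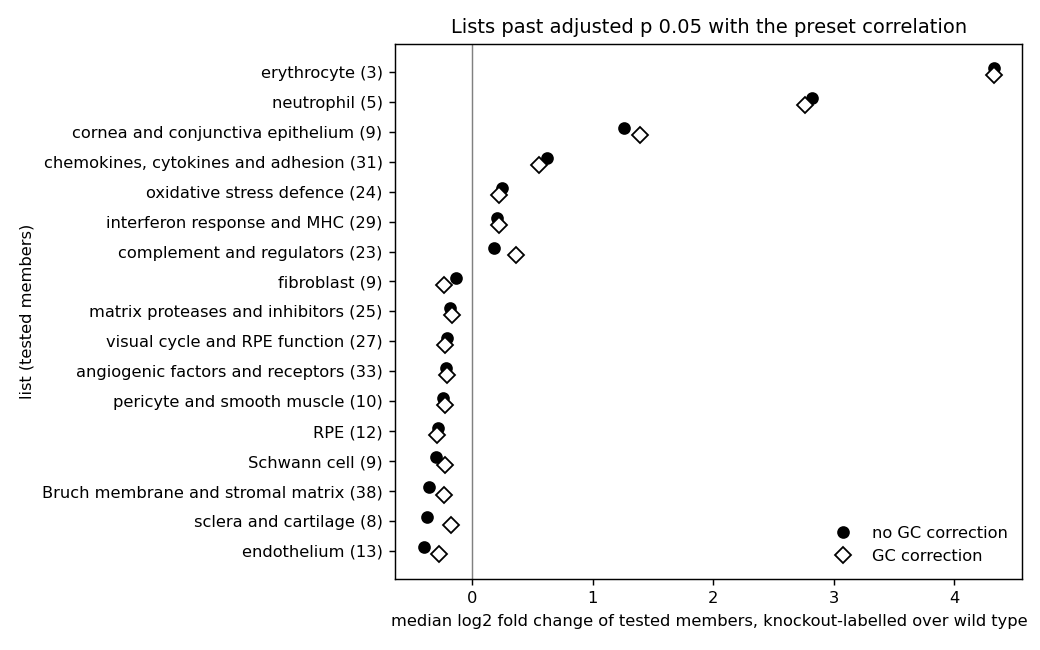
Median log2 fold change (knockout-labelled over wild type) of the tested members of the 17 lists called with the preset correlation, without (filled circles) and with (open diamonds) the GC correction. Of these lists 7 lie above 0 and 10 below, on the same side in both fits, and 15 were called in both.

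Markers of other tissues differed between the libraries. Epithelial markers of the cornea and conjunctiva, which lie outside the dissected tissue, were higher (median 1.26 over 9 members, camera adjusted p = 4.34e-06; adjusted p = 0.55 with an estimated correlation). Of these 0 were called and 8 passed adjusted over the list alone, among them Krt6a (1.45) and Krt13 (1.23). Without knockout-labelled animal 2 Krt13 was at 0.82. Krt12, the keratin gene of corneal epithelium, stood at 206, 4103 and 2903 CPM in knockout-labelled animals 1 to 3 and at 804, 511 and 302 CPM in wild-type animals 1 to 3. Erythroid markers were higher (median 4.33 over 3 members, camera adjusted p = 0.00347; adjusted p = 0.55 with an estimated correlation), with 0 called. All 3 passed adjusted over the list alone, among them Hbb-b1 (4.49) and Alas2 (4.33). Without knockout-labelled animal 1 these were 2.04 and 1.71, and Alas2 was at 2.74 with the sex covariate and 2.78 with the replicate block. With the cornea marker covariate Hbb-b1 and Alas2 were at 6.36 and 5.95, and both were called (edgeR adjusted p = 0.000795 each). Knockout-labelled animal 1 had the lowest cornea score of its group (7.85, against 9.80 and 9.54 in animals 2 and 3). Its erythroid score was the highest (8.11, against 4.51 and 4.95). The values with that covariate therefore rest largely on 1 library. Alas2, the haem synthesis enzyme of red cell precursors, stood at 847 CPM in knockout-labelled animal 1, 45.4 and 57.9 CPM in animals 2 and 3, and 3.76 to 27.4 CPM in the wild type.

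**Figure D4:**
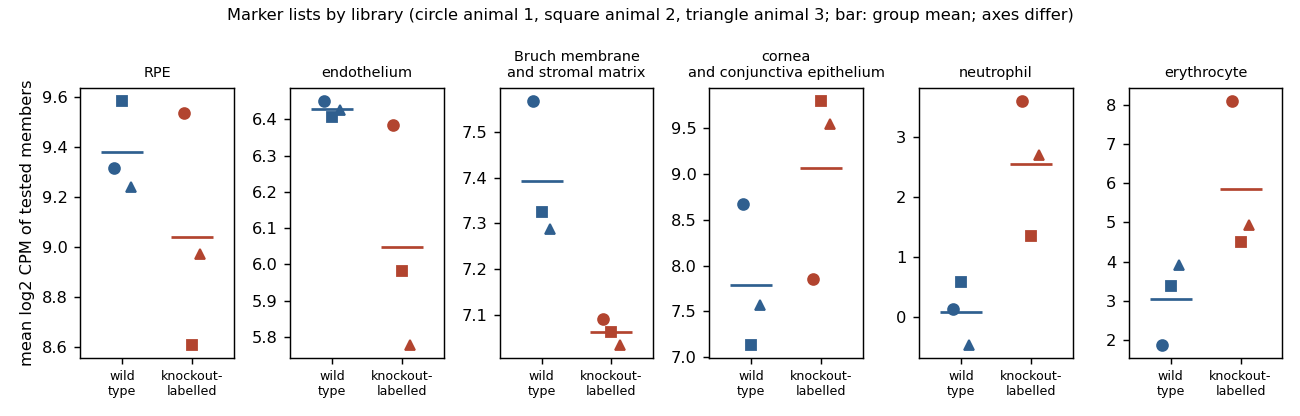
Mean log2 CPM of the tested members of 6 lists in each library, with a bar at each group mean (n = 3 animals; the vertical axes differ). The matrix list is at 7.03 to 7.09 in the knockout-labelled and 7.29 to 7.57 in the wild-type libraries, whereas for the cornea and conjunctiva list knockout-labelled animal 1 (7.85) lies below wild-type animal 1 (8.67).

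RPE markers were lower (median -0.28 over 12 members, camera adjusted p = 0.0251; adjusted p = 0.727 with an estimated correlation), as were visual cycle and RPE function genes (median -0.21 over 27 members, camera adjusted p = 0.00713; adjusted p = 0.727 with an estimated correlation). No member of either list passed, adjusted over all genes or over the list alone. Ttr and Trf, transport protein genes, stood at 16037 ± 4029 against 19285 ± 3459 CPM and at 7991 ± 3012 against 9509 ± 1785 CPM (SD, n = 3 each). Mean log2 CPM of the RPE markers was 9.54, 8.60 and 8.97 in knockout-labelled animals 1 to 3 and 9.24 to 9.58 in the wild type. Neither list was called with the cornea marker covariate, which turned their direction (medians 0.08 and 0.10, adjusted p = 0.43 and 0.228). Nor were they called without knockout-labelled animal 2 (0.373 and 0.282), knockout-labelled animal 3 (0.108 and 0.0859) or wild-type animal 2 (0.12 and 0.0624).

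The other 22 lists tested were not called. AhR target genes, such as drug-metabolising enzymes the receptor induces, had a median log2 fold change of 0.39 over 10 members (camera adjusted p = 0.0905; 0.568 with an estimated correlation). The list was called as higher without knockout-labelled animal 1 (adjusted p = 0.00241) or wild-type animal 1 (0.0382), while with the cornea marker covariate its direction turned (0.714). Aldh3a1, which corneal epithelium also makes in bulk, stood at 1984 ± 1441 and 664 ± 342 CPM in the knockout-labelled and wild-type libraries. It is also among the markers averaged in the cornea marker covariate, so the turn of the target list with that covariate was partly built in. Scin, another member of the target list, lies within 10 Mb of Ahr, so linked sequence may affect its log2 fold change of 1.24. Of the 10 tested members of that list, 8 lay above 0 and 2 below. Nqo1 stood at 90.7 ± 12.6 and 94.4 ± 4.23 CPM (SD, n = 3 each). Lipid and cholesterol genes were not called as a group (adjusted p = 0.925, with a median of -0.07, a mean of 0.01 and an upward test), and their median was 0.06 after the GC correction and 0.14 with the cornea marker covariate. Of 33 members 4 were higher when adjusted over the list alone, among them Idi1 (log2 fold change 0.87), Sqle (0.66) and Hmgcs1 (0.64), enzymes of sterol synthesis. In the same way Rab38 (0.55) passed among 12 melanogenesis genes (list adjusted p = 0.915) and Aldh1a3 (1.28) among 8 markers of the ciliary body and iris (list adjusted p = 0.356, and 0.00601 without wild-type animal 1), with 0 called in each of these 3 lists. With the cornea marker covariate Aldh1a3 was at 0.53.

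For the remaining gene lists the camera adjusted p was 0.906 for AhR complex partners, 0.9 for lysosome and autophagy, 0.588 for the circadian clock, 0.0905 for immediate early genes and 0.185 for Wnt and TGF-beta signalling. For the remaining markers it was 0.925 for melanocytes, 0.925 for mast cells, 0.588 for rods, 0.9 for cones, 0.553 for inner retinal neurons and 0.906 for Mueller glia and astrocytes. It was 0.0594 for skeletal muscle, 0.174 for lens, 0.268 for adipocytes, 0.489 for lacrimal and Harderian glands and 0.925 for sex-linked genes. Several of these lists were called under another setting. Immediate early genes were called as lower without knockout-labelled animal 3 (adjusted p = 2.8e-06) or wild-type animal 3 (0.00808) and with the cornea marker covariate (5.81e-07, where the median went from -0.22 to -0.65). Wnt and TGF-beta genes were called as lower with that covariate (0.000217, where the median went from -0.15 to -0.24) and without wild-type animal 3 (0.0396). After the GC correction neither list was called, and the medians were nearer 0, at -0.07 for immediate early genes (adjusted p = 0.486) and -0.03 for Wnt and TGF-beta genes (0.419). Muscle markers were called as higher with the GC correction (0.0284), the sex covariate (0.0159) and the replicate block (0.0194), and without knockout-labelled animal 3 (0.00044) or wild-type animal 3 (1.04e-07). Lens markers (median -0.14, against -0.02 after the GC correction and -0.78 with the cornea marker covariate) were called as lower without knockout-labelled animal 3 (9.53e-07) or wild-type animal 3 (0.00113). Without wild-type animal 3, markers of rods (3.35e-07), cones (0.0369) and adipocytes (0.000704) were called as higher, and those of rods also with the cornea marker covariate (0.0467). Median and test differed in sign for AhR complex partners, Mueller glia, sex-linked genes and melanogenesis. Dct, a pigment synthesis gene of melanocytes and RPE, stood at 4810 ± 316 and 4460 ± 1317 CPM and the muscle gene Mylpf at 393 ± 234 and 223 ± 153 CPM (SD, n = 3 each).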

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

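The test of the tally for reads aligned to more than 1 place was chosen after the tallies were seen. No comparison above uses that tally. As a share of each library's sum over all rows, it differed between the groups. Whether it holds each read once or once per alignment was not checked. The share was 23.9% ± 1.08 in the knockout-labelled and 19.0% ± 0.33 in the wild-type libraries (SD, n = 3 each). The knockout-labelled share was 4.84 percentage points higher, with no overlap between the groups. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. These reads are in no gene count.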

How the results depend on the processing

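The GC correction and the sex and cornea marker covariates were chosen after seeing the data. The 8 calls (4 higher, 4 lower) were the same genes with RLE factors, which called 8. Other settings called 15 (7 higher, 8 lower) with upper-quartile factors, 22 (9, 13) with no filter, 16 (7, 9) with the stricter filter, 493 (273, 220) with DESeq2, 13 (7, 6) with limma-voom, 352 (209, 143) with the exact test, 1 (1, 0) with sex as a covariate, 24 (14, 10) with the cornea marker covariate and 6 (5, 1) with the GC correction. At adjusted p under 0.1 there were 30 (14, 16), and under 0.01 there were 0 (0, 0), with 2238 at an unadjusted p under 0.05. All 8 genes remained in the upper-quartile, unfiltered, stricter, DESeq2 and exact fits. The causes were not tested. Leaving out 1 library gave 0 to 795 calls, 0 to 409 higher and 0 to 386 lower; the highest was without knockout-labelled animal 1, which kept all 8. Same-numbered animals did not deviate together (correlations -0.10, -0.09 and -0.07), which gives no sign of pairing by number. These values cannot exclude pairing, and animal 1 was female in both groups. With the number as a block 1 gene was called (1 higher, 0 lower), Ltf.

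Ahr kept its direction in all 17 alternatives and was past the threshold in DESeq2 (log2 fold change 0.95), the exact test (0.95) and without knockout-labelled animal 1 (0.97), with a range of 0.87 to 1.07 when 1 library was left out; adjusted p ran from 0.000208 to 0.374. Of lists, 17 were called in the main test, 0 with an estimated correlation, 0 with fry (lowest adjusted p = 0.171) and 12 to 20 when 1 library was left out; the block called 19 and lost none of the 17. Of the 22 lists not called, 11 were called in at least 1 alternative, in 28 cases and all in their original direction, and 11 in none. Calls within 10 Mb of Ahr were 3.03% of tested genes (Fisher's exact p = 0.000474), 4.55% within 5 Mb, 1.69% within 20 Mb, and 0% at adjusted p under 0.01, where no gene was called.

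Of 69 uncalled genes that the naming rule takes for their level, 35 turned sign in at least 1 alternative, 29 of them among the 50 not named. Among named genes the direction turned with the cornea marker covariate for Krt12 (-0.66), Aldh3a1 (-0.41), Ttr (0.14) and Trf (0.21), and when 1 library was left out for Dct (-0.14 to 0.24) and Nqo1 (-0.18 to 0.015). None of these genes was called in the main fit, and Krt12 and Aldh3a1 passed as higher in 1 alternative each. Krt12 and Aldh3a1 are among the markers averaged in that covariate, so their turn with it was largely built in. Aldh3a1 is in the AhR target list too. List directions turned with the cornea marker covariate for AhR targets (adjusted p = 0.714), RPE (0.43), visual cycle (0.228), ciliary body (0.386) and melanocytes (0.800); with the GC correction for cones (0.998), mast cells (0.998), melanocytes (0.778) and melanogenesis (0.759); and with the stricter filter for mast cells (0.91). Leaving out 1 library turned further lists in at least 1 fit. Each bracket gives the range of the camera adjusted p over all leave-one-out fits, turned or not. They were Mueller glia (0.383 to 0.984), cones (0.0369 to 0.984), inner retinal neurons (0.0868 to 0.881), lens (9.53e-07 to 0.966), lipid (0.42 to 0.994), lysosome (0.284 to 0.875), mast cells (0.332 to 0.829), melanocytes (0.284 to 0.994), melanogenesis (0.0987 to 0.994), rods (3.35e-07 to 0.906), sex-linked genes (0.391 to 0.766) and muscle (1.04e-07 to 0.859). No turned fit was called, and the values under 0.05 came from fits that kept the direction. Where lens and muscle turned, the camera adjusted p was 0.966 and 0.859. Depth limits genes near 1 CPM, such as S100a8 in the wild type.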

Other observations

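Tests chosen after the results were seen are those of the share of stroma and vessels, of linked sequence (its window and test were fixed earlier) and of blood, and the GC correction and marker covariates were also chosen after seeing the data. Because 4 sterol genes passed within the lipid list, a rise of the sterol synthesis pathway was set as a hypothesis. For it 22 other genes of that pathway or its regulation were listed before their values were looked at. Of 21 tested, 19 lay above 0 in the GC-corrected fit, with a median log2 fold change of 0.43 (bootstrap SE over genes 0.05), and 12 had an unadjusted p under 0.05. Camera in the edgeR fit gave p = 4.47e-10 with the preset and p = 0.0554 with an estimated correlation, so whether the genes may have risen together beyond the spread between animals stays open.

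The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 8 genes and the highest other split 13, so 2 of 10 gave as many. That other split set knockout-labelled animals 2 and 3 and wild-type animal 1, the 3 libraries with the highest cornea and conjunctiva scores, against the rest. For lists the real split called 17 and the highest other 21, and 3 of 10 gave as many.

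The lower matrix list was weighed against 3 technical explanations, with genotype as the biological one. After the GC correction the median stayed below 0, at -0.24 (SE 0.04 over members, before the correction -0.36, SE 0.05). The GC trend thus did not account for the whole of the lower median in these libraries. The calls of Eln (-1.39, SE 0.16, to -1.15, SE 0.16) and Chpf (-1.08, SE 0.12, to -0.72, SE 0.10) ended as their fold changes shrank. With the cornea marker covariate the median was -0.37 (SE 0.07), so the corneal score did not account for it either. The SEs of these medians are over genes that vary together and do not measure the spread between animals. After the GC correction the list's camera adjusted p was 0.435 with an estimated correlation. Whether the list lay lower beyond the spread between animals therefore stays open. A smaller share of stroma and vessels cannot be told apart from a change within them: melanocyte markers lay 0.25 (SE 0.10) above the matrix list, but RPE cells also make 4 of the 8, a reservation added after the values were seen, and the other 4 lay 0.29 above it with an SE of 0.22. Genotype stays open as well, and a smaller share of stroma may itself be part of it.

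Acp1 and Dgkb, 2 of the 8 called genes, lie within 10 Mb of Ahr. Of 66 tested genes in that window 2 were called (3.03%), against 6 of 15729 elsewhere (0.04%, two-sided Fisher's exact p = 0.000474). This is consistent with an effect of sequence linked to the targeted allele, and after the GC correction 1 of 66 was called (Fisher's exact p = 0.0248), the call of Acp1 ending (adjusted p = 0.0616) at a log2 fold change of -2.87 (SE 0.36) against -2.76 (SE 0.34) before. Lower alignment of reads with strain variants was to be excluded by 3 or more higher genes among those near Ahr at an unadjusted p under 0.01, and 3 of 6 were higher. That bound was wrong, since both called genes were lower and other genes do not bear on them, so alignment and expression cannot be told apart without reads, and regulation of these genes by the receptor was not tested.

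The rise of Ltf was weighed against carried-over epithelium and blood. With the cornea marker score as a covariate its log2 fold change was 4.03 (SE 0.45), which argues against corneal epithelium as the whole cause. All 8 tested conjunctiva markers were above 0 (log2 fold change 0.64 to 1.61) and their mean log2 CPM did not overlap between the groups (5.83 to 6.62 against 4.66 to 5.69). The highest of the 8, Agr2 (1.61), lies within 10 Mb of Ahr, so linked sequence may affect it and the score. With that score as a covariate the log2 fold change of Ltf was 3.65 (SE 0.61), above 0 by more than 2 SE. A score that does not overlap between the groups can hardly be told apart from genotype by a covariate. Carried-over conjunctiva therefore stays open. Blood stays open: without knockout-labelled animal 1, the highest in Alas2, the log2 fold change of Ltf went from 4.07 (SE 0.44) to 3.79 (SE 0.43) and that of Alas2 from 4.33 (SE 1.18) to 1.71 (SE 0.58), so Ltf moved far less, but Alas2 stayed above 0 by more than 2 SE. Gland tissue (3 markers, camera adjusted p = 0.489) and a change in the tissue's own cells may also contribute and stay open.

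Just short of a call, at an edgeR adjusted p of 0.0502, stood 7 genes, named after their values were seen. The log2 fold change was 2.27 for Arg1, 1.99 for Pglyrp1 and 1.07 for Prss27, and -1.21 for Wasf2, -0.91 for Tspan18, -0.91 for Cacna1g and -0.85 for Loxl1, which was at -0.53 after the GC correction.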
